A study of Mus musculus with 8 samples.

How the data were processed

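Total RNA from 8 lungs of mouse pups was isolated with the miRNeasy kit, amplified with the Agilent Low-Input QuickAmp kit and labelled with Cy3, per the labels' protocols. A table of 62976 array features in 8 columns was analysed. Its values are log2 signals as deposited. The scale was read from the values, which ran from 1.51 to 15.99. They had been quantile normalized between arrays by the authors, as the values show: the sorted values of complete features differed by at most 0.0042 between any 2 arrays. limma was used upstream, per the submitters' processing notes, which give no version. Background correction and flagging of dim or saturated spots are not given in the sources used here, so a difference near the floor (the median feature had a log2 signal of 3.47) or near the top of the scale is compressed by an unknown amount. Features had not been averaged or filtered. Between 10 and 26 features per array were blank, and 120 features with a blank on 1 or more arrays were left out.

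Features were named from the platform annotation: 31465 had 1 symbol, 0 had several and 31511 were not named there. Symbols were updated through unversioned transcript accessions against a RefSeq gene table (GRCm38.p6), which held 29050 of the named features and changed 2933 symbols. The array annotation names no genome build, so no coordinates are printed and the table was used only for names and for which genes neighbour each other. After 40 named features with a blank were left out, 31425 remained for 20842 genes, of which 6073 had more than 1 feature. The feature with the highest mean over all 8 arrays stood for its gene. Pairs of arrays with identical values numbered 0.

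Groups were taken from the titles and genotype labels, with 4 samples each. The main test, fixed with the gene lists, the naming rule and the alternatives before the data were examined, was limma 3.58.1 in R 4.3.3 (lmFit with group only, eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Standard errors are limma's moderated ones. Litter, sex, slide and scan date are not given in the sources used here, so no batch was tested. For Fgf10, Fgfr2 and Nnt a two-sided exact permutation test over all 70 assignments stood beside the fit. With 4 arrays per group, their number limits the precision. On data simulated with the residual spread of these 20842 genes, the same fit recovered 50 of 100 genes changed by a log2 of 1 and 80 of 100 changed by 2, with 11 false calls among 141.

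Named genes followed a fixed rule: Fgf10, Fgfr2 and Nnt always; the genes with the highest and lowest differences among those past the threshold, or, if fewer than 10 passed, the 10 with the smallest p, named as not passing; and from each list up to 4 members past 0.05 when adjusted over the list alone, or otherwise the 2 with the smallest p. The 39 lists fixed by name and the list of tested genes within 10 Mb of Fgf10 were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 40 lists, and again with a correlation estimated per list and with fry. In simulated lists of 20 genes, 5 of 5 shifted by a log2 of 0.5 were called and 0 of 35 unshifted ones. The simulated genes varied independently of each other, so this gives no rate of false calls for lists of correlated genes. Each list's median was also set against 10000 random lists matched on mean signal in 20 bins. Their genes were drawn independently of each other, so their range holds neither correlation between genes nor spread between libraries. "Rose" and "fell" refer to members past 0.05 when adjusted over their list alone.

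The alternatives were the mean of all features of a gene, every named feature on its own, further quantile normalization, centring on the median or the 75th percentile, leaving out genes below the 25th or the 50th percentile of mean signal, a variance trend with robust settings, array weights, the replicate number as a block, a sex covariate, and leaving out each replicate in turn. A pseudocount alternative planned for linear values did not apply, since the values are on a log scale. Leaving out wild-type replicate 4 together with replicate 3 of the libraries labelled Fgf10+/-, which lie at the ends of the second principal component, was added after seeing the data. Of the planned sex covariate genes, Ddx3y was not named on the array and Eif2s3y, Kdm5d and Uty were used with Xist. Figures were drawn with matplotlib 3.10.9.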

Results

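The data are gene expression profiles of lungs from newborn C57Bl/6J mouse pups that breathed 20% oxygen in a chamber from postnatal day 0 to day 3. RNA of 8 lungs was hybridised to 1-colour (Cy3) Agilent arrays, 4 from pups labelled wild type and 4 from pups labelled Fgf10+/-. The latter carry 1 disrupted copy of the gene for fibroblast growth factor 10. FGF10 is a growth factor made by lung mesenchyme that acts on the epithelium through the receptor FGFR2 and is needed for the lung to form. The comparison asks how a lung with a single intact Fgf10 copy differs from a wild-type lung in normal air. The submitters describe the 4 samples of each group as independent. The values are log2 signals that had been brought to a common distribution, and every array had a median of 3.47 over all 62976 features. Pairs of arrays correlated between 0.977 and 0.986 over the 20842 named genes, with a median of 0.982 both within and between the groups.

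The Fgf10 signal itself was not lower in the libraries labelled Fgf10+/-. It was 7.46 ± 0.40 (SD, n = 4) in the wild-type libraries and 7.95 ± 0.32 (SD, n = 4) in those labelled Fgf10+/-. The log2 difference of 0.49 had a standard error of 0.24 and did not pass (two-sided exact permutation p = 0.0857 over 70 assignments; limma adjusted p = 0.507). All 10 features named for Fgf10 had a higher mean in the libraries labelled Fgf10+/-, and their average differed by 0.31 (exact permutation p = 0.143). They read the same 8 RNAs, so they are not 10 independent measurements. Their differences ran from 0.07 to 0.49, so the feature that stood for the gene had the largest. Without wild-type replicate 3 the difference was 0.30. Where these features lie relative to the disrupted part of the gene is not given in the sources used here, so the signal may check nothing, and every direction below rests on the labels alone. Fgfr2, the main epithelial receptor of FGF10, had a log2 difference of -0.58 with a standard error of 0.19. Its 4 values in the libraries labelled Fgf10+/- all lay below the 4 wild-type values (two-sided exact permutation p = 0.0286, the smallest that 70 assignments can give; limma adjusted p = 0.318, which does not pass). Nnt encodes the mitochondrial transhydrogenase that is defective in the C57BL/6J strain, and it lies next to Fgf10 on chromosome 13. It was higher in all 4 libraries labelled Fgf10+/-, at 10.24 ± 0.06 (SD, n = 4) against 9.56 ± 0.04 (exact permutation p = 0.0286; limma adjusted p = 0.0767). When all features of the gene were averaged, the Nnt difference was 0.38 rather than 0.68.

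**Figure D1:**
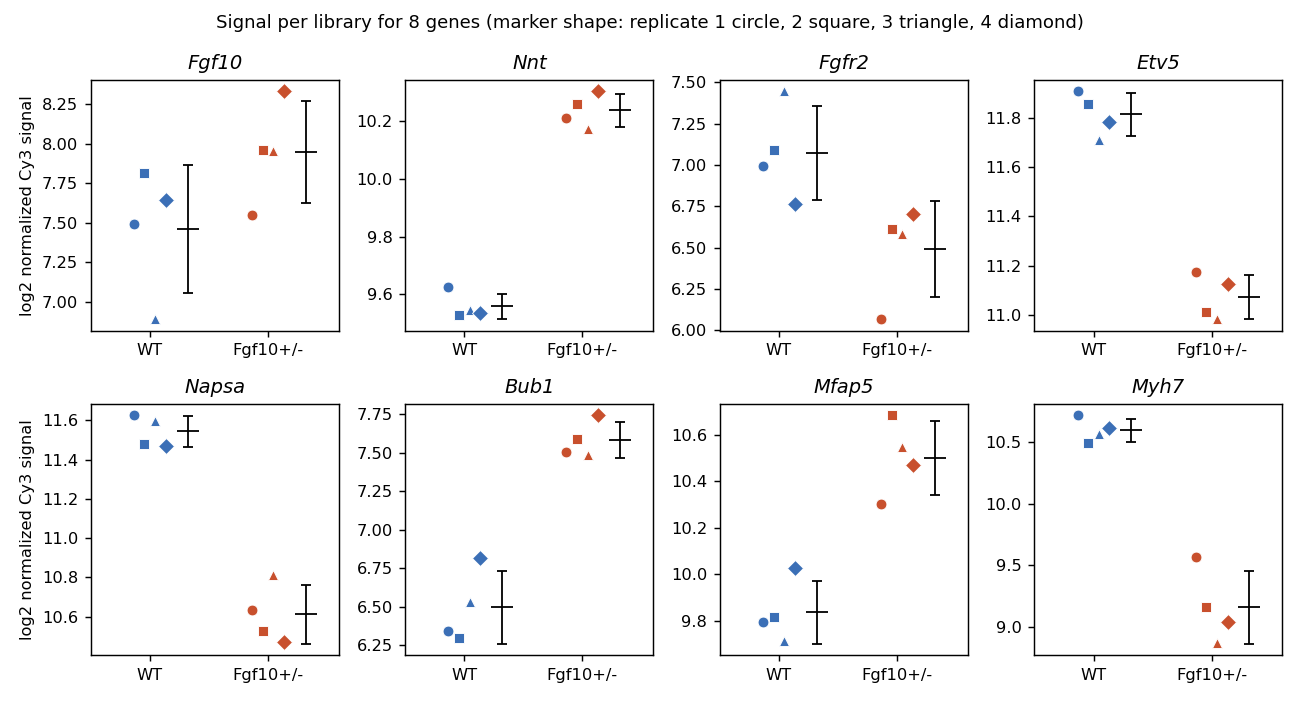
Normalized log2 Cy3 signal of 8 genes in each library (vertical axis), with the libraries labelled wild type in blue and those labelled Fgf10+/- in orange; the black bar is the mean with its SD (n = 4), and marker shape gives the replicate. The Fgf10 values of the groups overlap, while the Nnt values of the libraries labelled Fgf10+/- (lowest 10.17) all lie above the highest wild-type value (9.62).

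No single gene passed the test. Of the 10 genes with the smallest p, Pla2g1b, a secreted phospholipase, differed by -1.13 (SE 0.10), Scgb1c1, a secretoglobin, by -1.47 (SE 0.17), and Napsa, the aspartic protease that processes surfactant protein B in alveolar type 2 (AT2) cells, by -0.93 (SE 0.11) in the libraries labelled Fgf10+/-. Myh7, a cardiac and slow muscle myosin heavy chain, differed by -1.44 (SE 0.16) and Actn2, a muscle alpha-actinin, by -1.19 (SE 0.15), or by -0.71 when all features of the gene were averaged. Rap1gap, a brake on the small GTPase RAP1, differed by -0.996 and Bex4, a regulator of microtubules, by -0.73. On the other side, the mitotic kinase gene Bub1 differed by 1.08 (SE 0.14), the linker histone gene H1f5 by 0.90 (SE 0.10), and Sgo2a, a protector of centromeric cohesion, by 2.11 (SE 0.22), from a wild-type mean of 3.59, close to the array median. The groups did not overlap for any of these 10 genes, and each had an adjusted p of 0.0767 in limma.

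With limma and Benjamini-Hochberg adjustment over 20842 genes, 0 genes passed an adjusted p of 0.05, and 42 lay under 0.1, 10 higher and 32 lower. At an unadjusted p under 0.05 there were 2298 genes, 988 higher and 1310 lower, where chance gives about 1042. The groups did not overlap for 1540 genes, or 7.39%, where chance gives 2.86%. The single-gene count depended on the variance model and on the dim genes, since it was 414 with a variance trend and robust settings and 288 with the dimmer genes left out. Without wild-type replicate 4 the count was 1, Sgo2a.

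**Figure D2:**
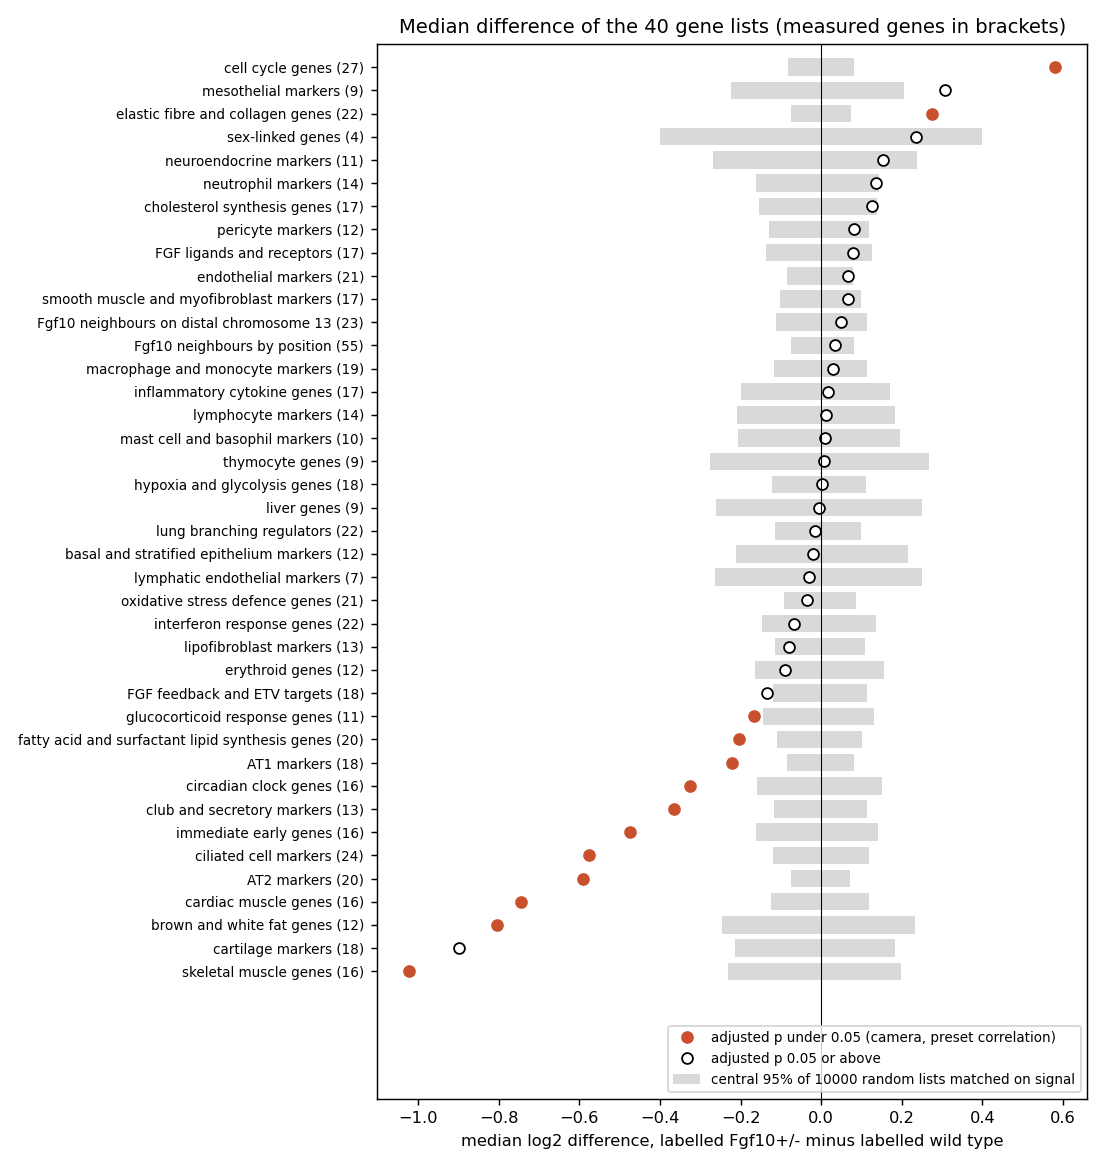
Median log2 difference (libraries labelled Fgf10+/- minus wild type, horizontal axis) of the measured genes of each of 40 gene lists; filled points have an adjusted p under 0.05 in camera with its preset correlation, and grey bars span the central 95% of medians of 10000 random lists matched on signal. AT2 markers, at -0.59, lay below their bar (-0.07 to 0.07) and cell cycle genes, at 0.58, above theirs (-0.08 to 0.08).

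AT2 markers were lower as a group in the libraries labelled Fgf10+/-. Their median log2 difference was -0.59 over 20 measured genes, all 20 of which had a lower mean. At an adjusted p under 0.05 over the list alone 16 fell while 0 rose and 4 did not pass. Besides Napsa, those that fell included Cebpa (-0.84), a transcription factor of maturing AT2 cells, Etv5 (-0.74), a transcription factor induced by FGF signalling, and Lpcat1 (-0.86), which makes surfactant phosphatidylcholine. Sftpc, chosen here after its values were seen, differed by -0.00, but its mean of 15.98 in both groups was at the top of the array scale, where the maximum was 15.99. The list passed camera, limma's set test, at an adjusted p of 2.35e-16 with the preset correlation, and had an adjusted p = 0.154 with an estimated correlation. The transcription factors Foxa1 (-0.54), Foxa2 (-0.65) and Nkx2-1 (-0.55), which maintain lung epithelial identity, fell over the list of lung branching regulators alone, while the list of 22 as a whole did not pass (camera adjusted p = 0.691) and its other 19 members did not pass. That list passed with every feature on its own (adjusted p = 4.16e-07), a setting in which a gene with several features counts several times.

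Ciliated, club and AT1 cell markers also passed camera as lower groups, while basal and neuroendocrine markers did not pass. Ciliated cell markers had a median of -0.58 over 24 genes. Of these 8 fell over the list alone, among them Cfap126 (-0.69), Ccdc40 (-0.83), Tppp3 (-0.48) and the axonemal dynein gene Dnah5 (-0.65), 0 rose and 16 did not pass (camera adjusted p = 2.29e-09; adjusted p = 0.409 with an estimated correlation). The Ccdc40 difference was -0.23 when all features of the gene were averaged. Club and secretory cell markers had a median of -0.37 over 13 genes. Of these 5 fell over the list alone, including Cyp2f2 (-0.42), a cytochrome P450 of club cells, Aldh1a7 (-0.63), Sec14l3 (-0.47) and Upk3a (-0.83), and 8 did not pass (camera adjusted p = 0.00108; adjusted p = 0.504 with an estimated correlation). That median was -0.23 without replicate 1 or without replicate 4 of the libraries labelled Fgf10+/-, and -0.24 without wild-type replicate 3. The club list member Scgb1a1, not named by the fixed rule, differed by -0.03. Its means of 15.96 (wild type) and 15.93 were near the top of the array scale. Markers of alveolar type 1 (AT1) cells, the flat cells of gas exchange, had a median of -0.22 over 18 genes. Of these 4 fell over the list alone, among them Ager (-0.55) and Gprc5a (-0.38), and 2 rose, Igfbp2 (1.37), which binds insulin-like growth factors, and Scnn1g (0.59), whose signal was near the floor, while 12 did not pass (camera adjusted p = 0.00473; adjusted p = 0.409 with an estimated correlation). The AT1 median was -0.14 without replicate 3 of the libraries labelled Fgf10+/-, and the list no longer passed, with an adjusted p of 0.0794, when that library and wild-type replicate 4 were both left out. In fry the AT1 list passed (adjusted p = 0.0348), but the ciliated and club lists did not (adjusted p = 0.0876 each). The mean log2 deviation of the club list was 0.16 in replicate 3 of the libraries labelled Fgf10+/-. In wild-type replicates 1 to 4 it was 0.12, 0.05, 0.32 and 0.09. The AT1 deviation was 0.04 in replicate 4 of the former group, above 0.02 in wild-type replicate 3. The ciliated groups were barely parted, at -0.0326 (replicate 3 of the former group) and -0.0274 (wild-type replicate 4).

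Cell cycle genes were higher as a group in the libraries labelled Fgf10+/-. Their median was 0.58 over 27 genes, and 17 rose over the list alone, 0 fell and 10 did not pass. Besides Bub1, those that rose included Cdk1 (0.90), the kinase that drives entry into mitosis, Ube2c (0.78) and Cdc20 (0.72), partners of the anaphase-promoting complex. The Cdk1 difference was 0.51 when all features of the gene were averaged. The list passed camera at an adjusted p of 6.40e-18, with an adjusted p = 0.154 with an estimated correlation. Genes of elastic fibres and collagens were also higher as a group, with a median of 0.27 over 22 genes, although only 1 member rose over the list alone, Mfap5 (0.66), which encodes a microfibril glycoprotein, and 21 did not pass (camera adjusted p = 2.49e-07; adjusted p = 0.447 with an estimated correlation).

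Genes of heart-type muscle were lower as a group in the libraries labelled Fgf10+/-. All 16 cardiac muscle genes had a lower mean, with a median of -0.74. Over the list alone 10 fell, among them Myh7, the cardiac myosin gene Myh6 (-0.84) and the troponin genes Tnnt2 (-0.81) and Tnnc1 (-0.86), and 6 did not pass (camera adjusted p = 1.89e-09; adjusted p = 0.154 with an estimated correlation). Skeletal muscle genes had a median of -1.02 and genes of brown and white fat a median of -0.80, and the calls of both lists rested on 1 library. The mean log2 deviation of the skeletal muscle list was 3.14 in wild-type replicate 4 and at most -0.35 in the other 7 libraries, and that of the fat list was 1.48 there and at most 0.07 elsewhere. Of the 16 skeletal muscle genes 0 passed over the list alone, the smallest p belonging to Atp2a1 (-0.74) and Eno3 (-0.58). Of the 12 fat genes 3 fell over the list alone, Cidec (-1.60), Plin5 (-0.76) and Cox7a1 (-0.94). Camera gave adjusted p of 0.00350 for skeletal muscle and 0.00699 for fat, with adjusted p = 0.796 and adjusted p = 0.544 with an estimated correlation. Without wild-type replicate 4 their medians were -0.06 and -0.14, with adjusted p of 0.449 and 0.436, so neither passed. Cartilage markers, with Chad (-1.30) and Matn3 (-0.59, or -0.38 without wild-type replicate 4) at the smallest p, stood at 3.10 in the same library and at most -0.40 in the others, and did not pass (camera adjusted p = 0.0666). The cartilage list passed when wild-type replicate 1 (0.0126), 2 (0.00760) or 3 (0.0110) was left out, and with further quantile normalization, median centring or a variance trend (0.0255). Without wild-type replicate 4 its adjusted p was 0.999.

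**Figure D3:**
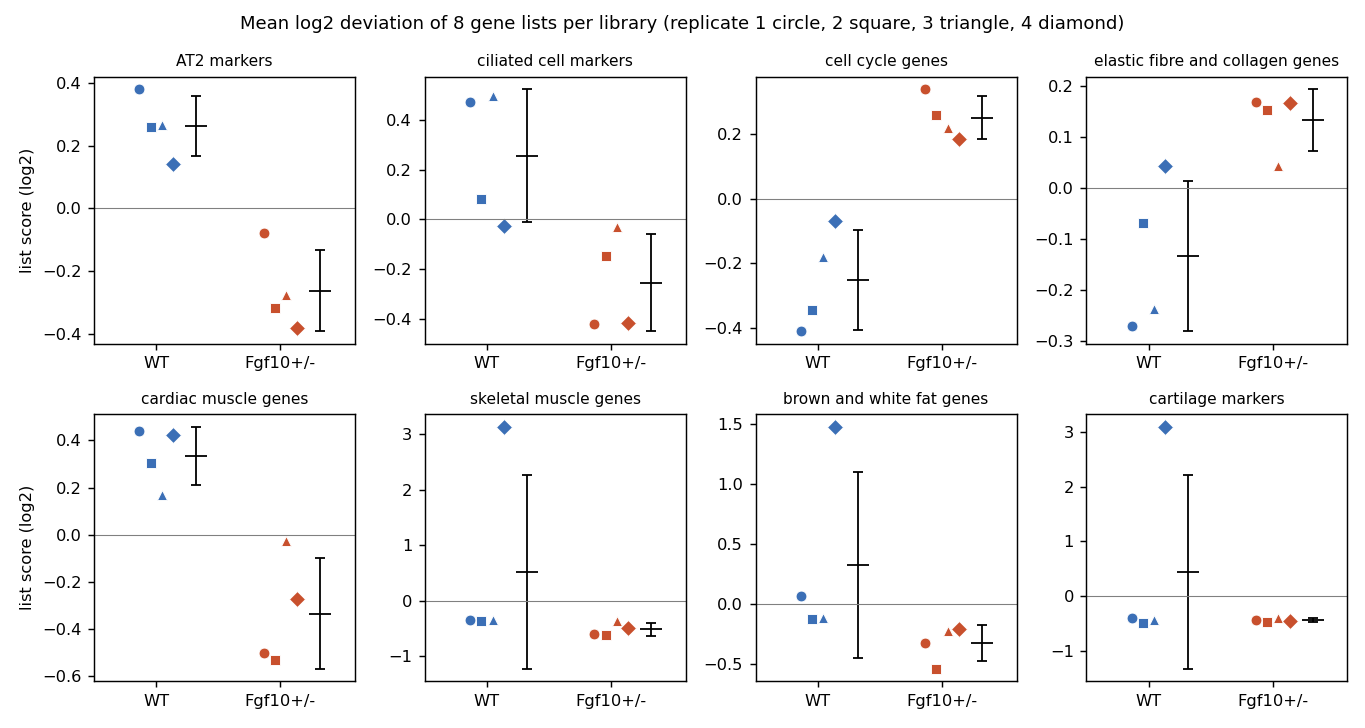
Mean log2 deviation from the average of all libraries for 8 gene lists (vertical axis) in each library, blue for wild type and orange for the libraries labelled Fgf10+/-; the black bar is the mean with its SD (n = 4), and marker shape gives the replicate. AT2 markers and cell cycle genes separated the groups without overlap, while skeletal muscle, fat and cartilage genes stood apart in wild-type replicate 4 (3.14, 1.48 and 3.10).

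Among the lists of signalling and metabolism, the circadian clock and lipid synthesis lists had lower medians in the libraries labelled Fgf10+/- and passed camera. The 16 clock genes, 11 with a lower and 5 with a higher mean, had a median of -0.33. Of these 4 fell over the list alone, Nr1d2 (-0.63), Dbp (-1.13), Cry2 (-0.65) and Per3 (-0.89), all members of the rhythmic output and feedback loops, and 12 did not pass (camera adjusted p = 0.0111; adjusted p = 0.159 with an estimated correlation). Of 20 genes of fatty acid and surfactant lipid synthesis, with a median of -0.20, Lpcat1 fell and 19 did not pass (camera adjusted p = 0.00769; adjusted p = 0.154 with an estimated correlation). Immediate early genes had a median of -0.47 over 16 genes. Of these Btg2 (-0.55) and Arc (-0.66) fell over the list alone and 14 did not pass (camera adjusted p = 0.00259; adjusted p = 0.508 with an estimated correlation). Glucocorticoid response genes had a median of -0.17 over 11 genes. Of these Zbtb16 (-0.80), Errfi1 (-0.69) and Klf9 (-0.50) fell over the list alone and 8 did not pass (camera adjusted p = 0.0225; adjusted p = 0.504 with an estimated correlation). This last call was lost without wild-type replicate 1 (adjusted p = 0.0628), or without replicate 2 (adjusted p = 0.132) or replicate 4 (adjusted p = 0.0752) of the libraries labelled Fgf10+/-. Without that replicate 4 the median was -0.10, and without replicate 1 of the same group it was -0.29. The clock list no longer passed, with a median of -0.23 and an adjusted p of 0.101, when wild-type replicate 4 and replicate 3 of the libraries labelled Fgf10+/- were both left out, and the lipid list did not pass when all features of a gene were averaged (median -0.14, adjusted p = 0.120). With genes below the median signal left out, the immediate early (adjusted p = 0.103), clock (0.110), glucocorticoid (0.0571), skeletal muscle (0.0760) and fat (0.0760) lists did not pass. The glucocorticoid list also did not pass with every feature on its own (median -0.05, adjusted p = 0.166) or with a sex covariate.

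Genes of the FGF pathway did not pass as groups. Among 18 feedback genes and ETV targets of FGF signalling, Etv5 fell over the list alone and 17 did not pass (camera adjusted p = 0.241). The list median of -0.13 lay just below the central 95% of matched random lists (-0.12 to 0.11). That range holds no correlation between genes and is not adjusted over the 40 lists, so it decides nothing here. Of 17 FGF ligands and receptors 0 passed over the list alone, and the 2 with the smallest p were Kl (0.46, near the floor) and Fgfr2 (camera adjusted p = 0.811). Genes near Fgf10 on chromosome 13 did not pass as groups either, with camera adjusted p of 0.152 for the 23 measured genes fixed by name and 0.811 for the 55 genes within 10 Mb, but single neighbours differed in both directions. Over these lists alone, Nnt and Paip1 (0.74) rose and Emb (-0.80), 4833420G17Rik (-0.78) and AF067061 (-0.69) fell, with 20 of the 23 and 51 of the 55 not passing. The Paip1 difference was 0.15 when all features of the gene were averaged.

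Markers of the other lung cell types did not pass in the main setting. For the vessels, camera gave adjusted p of 0.618 for endothelial markers, with Aplnr at 0.27 and Gpihbp1 at -0.30, 0.864 for lymphatic markers, with Reln at -0.51 and Stab2 at 0.30, and 0.406 for pericyte markers, with Rgs5 at 0.49 and Abcc9 at 0.23. For the mesenchyme it gave 0.671 for smooth muscle and myofibroblast markers, with Acta2 at 0.23 and Enpp2 at -0.52 (0.00203 with every feature on its own), and 0.433 for lipofibroblast markers, with Cd36 at -0.40 and Lpl at -0.30. Mesothelial markers, with Lrrn4 at 1.20 and Msln at 0.26, had 0.137 with a median of 0.31, above their matched random lists (-0.22 to 0.21), and passed at 5.82e-06 without replicate 3 of the libraries labelled Fgf10+/-, whose mean deviation for that list was -1.16. Basal and stratified epithelium markers, with Krt15 at -1.79 and Sprr3 at 0.64, had 0.951, and neuroendocrine markers, with Meis2 at 0.34 and Calca at -0.55, had 0.691. Several of these single values, none of which passed, hung on 1 library: with each replicate left out in turn Reln ranged from -0.72 to -0.27, Stab2 from 0.12 to 0.46, Abcc9 from 0.10 to 0.30, Msln from 0.06 to 0.49, Sprr3 from 0.41 to 0.74 and Calca from -0.71 to -0.33. Without both wild-type replicate 4 and replicate 3 of the libraries labelled Fgf10+/-, Calca was at -0.17 and Lrrn4 at 1.84.

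Blood and immune cell markers did not pass either. Camera gave adjusted p of 0.808 for macrophage and monocyte markers, among which Ear2 (-0.89), an eosinophil-associated ribonuclease of alveolar macrophages, fell over the list alone. It gave 0.835 for neutrophil markers (Mcemp1 -0.58, Csf3r 0.09), 0.984 for lymphocyte markers (Cd2 -0.35, Cd5 -0.26), 0.951 for mast cell and basophil markers (Tpsb2 0.34, Mcpt8 -0.79), 0.887 for erythroid genes (Rhd -0.44, Hemgn 0.11; 0.0472 without replicate 3 of the libraries labelled Fgf10+/-) and 0.951 for thymocyte genes (Themis -0.25, Ptcra 0.55). Interferon response genes had 0.951, with Gbp2 at 0.53 and Cxcl10 at 1.16, and inflammatory cytokine genes 0.951, with the chemokines Ccl2 at 0.65 and Ccl7 at 1.23. Of these single values, Cxcl10 ranged from 0.61 to 1.57 with each replicate left out in turn, and was 0.45 when all features of the gene were averaged. In the same way Rhd ranged from -0.67 to -0.17, Hemgn from 0.03 to 0.17, Themis from -0.40 to -0.08, Ptcra from -0.14 to 0.90, Cd5 from -0.36 to -0.15 and Csf3r from 0.03 to 0.16.

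Of the remaining lists, oxidative stress defence genes (adjusted p = 0.808; 0.0218 with every feature on its own) held Nnt, which rose over the list alone, and the metallothionein gene Mt1 (-0.68), which fell. Hypoxia and glycolysis genes (0.338) held Bnip3 (-0.50), and liver genes (0.808) held the transferrin gene Trf (-0.53), both of which fell over the list alone. Cholesterol synthesis genes had an adjusted p of 0.0594, with Hmgcs1 at 0.26 and Sc5d at 0.37 (0.22 without wild-type replicate 1), and passed without wild-type replicate 1 (0.0240), wild-type replicate 3 (0.00904) or replicate 3 of the libraries labelled Fgf10+/- (0.0320), as well as under 6 of the other settings, among them the sex covariate (0.0259). Sex-linked genes had 0.951, with Xist at -1.40 and Uty at 0.42; with each replicate left out in turn these ranged from -2.35 to -0.62 and from -0.15 to 0.82, and with the sex covariate Xist was at -0.32. In all, 13 of 40 lists passed camera with the preset correlation, 2 higher and 11 lower, 0 passed with an estimated correlation, and 6 passed fry, which tests each list without setting it against other genes. Over all genes, 0 members of any list passed. Median, mean and camera direction differed in sign for the smooth muscle, macrophage, mast cell, lymphocyte, interferon, hypoxia and sex-linked lists, none of which passed.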

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

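For Fgf10 and Nnt, the tests of neighbouring genes, of a wrong label and of the features were chosen after the result was seen; for AT2 and cell cycle genes, so were those of signal intensity, of AT1 markers and of endothelial markers; and so was the comparison of the strongest list in each split. The tests of pan-epithelial, fetal growth, ventricular and atrial genes were fixed before their values were seen.

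Single libraries stood apart within their group of 4 for 15 of 274 sets of values, where about 14 are due by chance; the number given is the gap to the nearest library over the range of the group. In wild-type replicate 4 these were the list scores of skeletal muscle (0.994), cartilage (0.976) and fat genes (0.882), all higher, with Actn2 higher (0.882) and Cry2 lower (0.962). In replicate 3 of the libraries labelled Fgf10+/- they were Actn2 (0.888) and Sec14l3 (0.907), both higher, and the elastic fibre and collagen score, lower (0.874). Kl was lower in replicate 4 of that group (0.900), and Sprr3 (0.843) and Klf9 (0.881) were higher in its replicate 1. Per3 was lower in wild-type replicate 3 (0.840). In wild-type replicate 2 Xist was lower (0.888), Uty higher (0.879) and the erythroid score lower (0.967).

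The Fgf10 signal was not lower, and Nnt beside it was higher, in the libraries labelled Fgf10+/-. A single library under the wrong genotype label cannot be told apart: the Nnt values of the groups were parted by a gap of 0.55, but that gap is part of the pattern, and Nnt marks the genotype only if a linked stretch does. A stretch of another strain carried along with the disrupted allele stays open: 8 of the 36 tested genes nearest to Fgf10 had p under 0.05 in either direction, or 22.2%, above the 95th percentile (19.4%) of 19800 runs of as many genes along the genome, although several of these neighbours had been seen beforehand. C57BL/6J carries a defective Nnt, so such a stretch may bring an intact copy, which was not tested. Whether the Fgf10 features also read a transcript of the disrupted allele cannot be told apart from an unchanged level, since their mean difference of 0.31 lies on the side that decides nothing and their place in the gene is unknown here.

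AT2 markers were lower and cell cycle genes higher in the libraries labelled Fgf10+/-. A shift that follows signal intensity is argued against, since matched random lists reached only -0.0740 at their lower 95% bound for AT2 markers. A lower share of epithelium may account for part of it: 19 pan-epithelial genes, none of them in another list, all had lower means, with a median of -0.48 (95% bootstrap interval over genes, -0.62 to -0.41) beside -0.59 (-0.75 to -0.39) for AT2 markers. The AT1 median of -0.22 (-0.30 to -0.06) lay above the AT2 interval. The intervals of ciliated (-0.67 to -0.43) and club markers (-0.47 to -0.05) overlapped the AT2 interval. All these intervals resample genes and hold no spread between libraries, so an equal loss of every epithelial type cannot be told apart. The endothelial median of 0.0669 (-0.03 to 0.12) lay below that of cell cycle genes, 0.58 (0.26 to 0.65). But the mesothelial interval (0.24 to 0.60) overlapped that of cell cycle genes. The cell cycle median was above the endothelial one over these genes, but these intervals too hold no spread between libraries. A larger share of another cell type cannot be told apart. For a later developmental state of the wild-type lungs, 20 fetal growth genes that decline after birth went both ways, 8 higher and 12 lower. Their median was -0.0300 (-0.21 to 0.08). The rule fixed beforehand counted a median that was not positive against this explanation, and the median met it. But the interval, which was not part of that rule, held both signs, so the evidence against it is weak. The genotype itself stays open and was not tested apart from these.

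Cardiac muscle genes were lower in the libraries labelled Fgf10+/-. Less atrial or pulmonary vein muscle in the sample cannot be told apart: the atrial genes Myl7, Myl4, Nppa, Sln and Bmp10 all had lower means, with a median of -0.65, but 4 of these 5 genes are in the cardiac list itself and Bmp10 alone differed by only -0.15. Less ventricular tissue taken with the lung cannot be told apart, since Myl2 and Myl3, both in the cardiac list, averaged -0.31 with standard errors of 0.82 and 0.33, while Irx4 (0.25) and Hey2 (0.49) had higher means from wild-type signals of 2.54 and 2.93, below the median feature. Whether such muscle varied through dissection or through genotype was not tested.

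All 35 ways to split the 8 libraries into 4 and 4 were tried. Each of the 35 splits, real or not, had lists that passed camera at the preset correlation. The strongest of the 40 camera tests had a -log10 p of 18.8 in the real split, for cell cycle genes, and at most 11.8 in the others, so 1 of 35 splits, the real one, gave a list as strong; the AT2 markers, at 16.9, also lay above every other split. For these 2 lists a split by chance is unlikely at 0.05, where 1 of 35 is the smallest share that the splits can give. An unlabelled structure of the samples is not excluded by this. Their median sizes, 0.58 and 0.59, were also above the highest others, 0.43 and 0.44. Cardiac muscle genes and ciliated cell markers had their largest medians in the real split (0.74 and 0.58, highest others 0.67 and 0.57), but they were picked for small p among 40 lists, and 7 of 35 splits held some list as strong, so chance is not excluded for them. For elastic fibre and collagen genes 2 splits gave a median as large (real 0.27, highest other 0.29), 6 splits gave as many lists (real 13, highest other 17), and 2 gave as many genes with p under 0.05 (real 2298, highest other 2873), so chance cannot be excluded there. For the number of genes past the threshold the splits decide nothing, since the real count was 0 in limma. A single other split called genes, 36 of them, and it points to a structure of the samples: it joined replicate 1 of the libraries labelled Fgf10+/- with wild-type replicates 1, 2 and 3, as did the sign of the first principal component. No label names a batch that follows it.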

How the results depend on the processing

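The joint removal of 2 libraries and the splits for the variance trend and for the dimmer genes were chosen after the result was seen. The count of genes past the threshold depended on the processing. It was 0 in the main setting, 38 (8 higher, 30 lower) without genes below the 25th percentile, 288 (93 higher, 195 lower) without those below the 50th percentile, 414 (148 higher, 266 lower) with a variance trend and robust settings, 3 with array weights, and 0 to 1 when 1 replicate was left out; it was 0 under the other settings run. In the filtered runs fewer and brighter genes were tested, and from the dimmest to the brightest 25% of genes the median residual SD was 0.441, 0.529, 0.228 and 0.129; 228 genes were shared by the 414 and the 288. With the trend 2 of 35 splits gave as many genes, the highest other being 632, so chance cannot be excluded for that count; without the dimmer genes the highest other was 534. Genes with p under 0.05 numbered 1822 to 2816 over all gene-level settings, and 1822 to 2658 when 1 replicate was left out. The number of lists that passed was 13, 0 with an estimated correlation, 6 with fry, 11 to 16 when 1 replicate was left out, 9 to 15 under the other planned settings, and 10 without the 2 libraries chosen after seeing the data. The replicate number as a block gave 0 genes and 13 lists. Same-numbered libraries had residual correlations of 0.113, 0.0226, 0.0178 and 0.0776. Libraries with different numbers were not set beside them, so whether the numbers pair the samples cannot be told. The Fgf10 difference was 0.31 to 0.55 over the planned settings and 0.30 to 0.62 when 1 replicate was left out, and never passed. Of 879 values for lists, 821 were called as in the main setting, 37 lost and 21 gained a call. A change of sign was looked for only in the 13 lists that passed in the main setting, where 0 turned. It was not looked for in the other lists, nor with fry or an estimated correlation. Of 1890 values for single named genes, 1784 kept their side, 102 gained a call and 4 turned, none past the threshold: Tpsb2 with all features averaged (-0.00961), Uty with the sex covariate (-0.0538) and without replicate 4 of the libraries labelled Fgf10+/- (-0.15, beside 0.82 without replicate 3), and Ptcra without replicate 1 of that group (-0.14, beside 0.90 without replicate 2). The cause was not tested. With no background flags at hand, signals near the median feature (3.47) have little precision.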

Other observations

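The genes, families and histone group described here were chosen after the result was seen. With the variance trend and robust settings, under which 414 genes passed, of 20842 tested, members of several lists passed in the libraries labelled Fgf10+/-. Of 20 AT2 markers 13 fell and 0 rose, of 18 AT1 markers 5 fell, of 13 club and secretory markers 5 fell, of 16 cardiac muscle genes 5 fell, of 27 cell cycle genes 16 rose and of 22 elastic fibre and collagen genes 5 rose. Of 24 ciliated cell markers only 3 fell, as did 3 of 16 clock genes and 3 of 22 lung branching regulators; among the genes near Fgf10, 2 rose and 1 fell of the 23 fixed by name, and 2 rose and 2 fell of the 55 by position. Every other list had at most 2 members that passed. Genes outside the lists, chosen after their values were seen, included Igf1, a mesenchymal growth factor (0.80, adjusted p = 0.000112), the epithelial transcription factor Elf5 (-0.93, adjusted p = 0.00025), the homeobox gene Irx3 (-0.83, adjusted p = 0.00031) and the surfactant-associated gene Sfta2 (-0.76, adjusted p = 0.000387). In limma's main fit these 4 genes did not pass, with adjusted p of 0.0767 for Igf1, Elf5 and Irx3 and 0.14 for Sfta2.

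Clustered histone genes, which are transcribed mainly during DNA replication, were looked at after H1f5 was seen among the 10 smallest p. Of 43 measured, 33 had a higher and 10 a lower mean in the libraries labelled Fgf10+/-, with a median of 0.26, and 14 had p under 0.05 in limma with a higher mean against 0 with a lower one. Examples were H2ac4 (0.50), H2bc4 (0.62) and H2bc1 (0.67). These genes are close copies and a feature for 1 can read others, so they are not 43 separate measurements.

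Genes were also grouped by the stem of their symbol, which gave 325 families, a grouping chosen after seeing the data. With camera at its preset correlation 4 passed, all lower in the libraries labelled Fgf10+/-: Cfap, cilia and flagella proteins (28 genes, median -0.48), Dnah, axonemal dynein heavy chains (9 genes, -0.58), Myh, myosin heavy chains (14 genes, -0.73), and Kcnj, inward rectifier potassium channels (15 genes, -0.40), whose median signal of 2.83 is near the floor. With an estimated correlation 0 passed. The Cfap and Dnah families share genes with the ciliated cell list, among them Cfap126 and Dnah5, so they are not separate evidence beside it. The Myh family takes in myosins of the skeletal muscle list, whose call rested on wild-type replicate 4. The families were not tested without that library. Among the 31431 complete features that the annotation does not name, 0 passed in limma, with a lowest adjusted p of 0.767, and 1868 had p under 0.05.

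On the first principal component, which held 20.5% of the variance, replicate 1 of the libraries labelled Fgf10+/- lay with wild-type replicates 1, 2 and 3 (-22.1 beside -30.1, -19.2 and -31.1), and wild-type replicate 4 lay with the others (30.1 beside 17.7, 37.3 and 17.5). On the second, with 17.7%, replicate 3 of the libraries labelled Fgf10+/- (39.1) and wild-type replicate 4 (-51.8) lay at the ends. The levels of Xist and Eif2s3y divided the libraries across both groups: the mean of Eif2s3y, Kdm5d and Uty minus Xist was above 0 in wild-type replicate 2 and in replicates 2 and 4 of the libraries labelled Fgf10+/-, at 2.27, 3.00 and 3.65, and between -4.45 and -3.28 in the other 5.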
